A study of Mus musculus with 7 samples.

How the data were processed

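RNA was measured in 7 samples of Treg cells sorted from mouse melanomas, 4 labelled FOXP3-low and 3 labelled FOXP3-high. Per the labels' protocols, RNA was extracted with TRIzol and made into stranded mRNA libraries from 100 to 200 ng of total RNA. The file holds whole-number counts per gene, which the authors deposited without normalization as one table of 57180 genes with gene coordinates and length. Per the submitters' processing notes, the tools were fastp 0.23.4, STAR 2.5.3a and featureCounts, and the builds were GRCh38 and GRCm39; the deposited coordinates are those of mouse genes and are given here as GRCm39. The gene length column holds one deposited value per gene in bases, as the authors' counting tool wrote it, and was used only in a check of length bias. The strand setting, the handling of reads shared between genes, and any collapsing of duplicate reads by molecular identifiers are not given in the sources used here. Counts of overlapping, antisense and near-identical genes are therefore uncertain, and overlaps with a gene holding at least 10% as many counts are named in the text. The unmapped columns of sample values numbered 0, and no row lacked a gene name.

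Groups and replicate numbers came from the sample titles. Total counts were 12177761 to 14546999 in FOXP3-low and 9048771 to 11202260 in FOXP3-high, so that a gene at 1 CPM rests on about 9 counts in the smallest library and 14 in the largest. Counts of replicates of one group differed by more than Poisson counting noise in every pair, with a chi-square per gene between 3.98 and 12.2 over genes with at least 20 counts in the pair. No pair therefore looked like copies of the same counts, and all 7 were kept as the labels number them, although duplicate reads or repeat libraries can also exceed counting noise. Mitochondrial genes took 0.565% to 0.689% of counts, and T cell receptor and immunoglobulin segments 0.0969% to 0.192%.

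Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group and its defaults (a minimum count of 10 and a total of 15), which left 15838, and libraries were normalized by TMM with factors between 0.973 and 1.05. The quasi-likelihood test (glmQLFit, glmQLFTest) compared FOXP3-high with FOXP3-low without a block, and p-values were adjusted by Benjamini-Hochberg over all genes tested at a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM library sizes. The common biological coefficient of variation was 0.178.

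Gene lists (45 lists) were written from general knowledge of T cells and tumours before the data were examined, as were the design and the first set of alternatives. Of their 899 entries, 883 matched a symbol in the file, 2 matched a symbol on several rows, of which the row whose gene ID the GENCODE M21 names pair with the symbol was used, and 14 were found by the gene ID of an older symbol. For each list the members called over all genes, the members called when adjusted over the list alone, and the median log2 fold change are given. Camera in limma 3.58.1 with a preset correlation of 0.01 on voom log2 CPM, adjusted over the 44 lists with at least 3 tested members, tested whether a list moved more than other genes. Camera with an estimated correlation and fry stand beside it.

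The named genes followed a rule set before the data were examined. They are Foxp3; the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups' libraries; and in each list up to 4 members with the smallest adjusted p under 0.05, or the 2 with the highest mean CPM where none passed. Predicted genes (Gm or LOC numbers, Rik clones), pseudogenes, receptor and immunoglobulin segments, mitochondrial and histone genes did not enter the 10 largest changes. Genes named outside the rule are said to have been chosen after their values were seen.

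The alternatives set at that time were DESeq2 size factors, upper quartile factors and total counts in place of TMM; no filter and a filter of at least 50 counts in each of 3 libraries; the DESeq2 1.42.0 Wald test, limma-voom, and limma-voom with sample quality weights; glmTreat against an absolute log2 fold change of 1; leaving out each library in turn; a replicate block; and leaving out receptor segments and mitochondrial genes. For lists, members that another list also holds were left out as well. After the data were seen, scaling to the 17 T cell identity genes, a loess correction (span 0.4) for gene length and transcript GC content, and leaving out both libraries numbered 3 were added. GC content came from the longest GENCODE M21 transcript of each gene ID, which covered 97.3% of tested genes, and no coordinates of that build were used.

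The edgeR step was tested on simulated counts for the 15838 genes with the real means, dispersions and library sizes of this comparison, in 3 runs with 200 genes changed per run. It recovered 17.4% of genes changed by a log2 fold change of 0.5, 55.7% at 1 and 85.4% at 2, and 8.1% of its 344 calls were false. The data called far more genes, 7357, than the 200 changed per run. The cut-off on p was therefore stricter in the simulation than in the data. The camera step called the shifted list in each of the 3 runs and none of 6 unchanged lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.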

Results

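Tumour-infiltrating regulatory T cells (Treg cells, the CD4 T cells that restrain immune responses and depend on the transcription factor FOXP3) were sorted from B16-F0 melanomas, a transplantable mouse melanoma, into a FOXP3-high and a FOXP3-low population. The mice carried a Foxp3 reporter in which YFP and Cre recombinase are expressed from the Foxp3 gene. The labels do not give the gates or markers of the sort, so the purity of the sorted cells was not checked. Bulk stranded mRNA libraries were counted per gene in 4 FOXP3-low and 3 FOXP3-high samples. Library totals ran from 12177761 to 14546999 counts in FOXP3-low and from 9048771 to 11202260 in FOXP3-high. The labels do not say whether the samples of a group came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Values are CPM (counts of a gene scaled to the TMM-normalized size of its library) as mean ± SD over n = 4 FOXP3-low and n = 3 FOXP3-high libraries, and log2 fold changes are FOXP3-high minus FOXP3-low with their standard error.

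Foxp3 itself, the gene whose level names the groups, followed the labels in each library. Foxp3 (ENSMUSG00000039521, chromosome X, 7439883 to 7461473, plus strand, GRCm39) was at 357 ± 44.3 CPM in FOXP3-low and 698 ± 95.4 CPM in FOXP3-high. The lowest FOXP3-high library, at 639 CPM, lay above the highest FOXP3-low library, at 397 CPM. The log2 fold change was 0.97 ± 0.11, a 1.95-fold difference (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.47e-05). This is a check of the labels and not a result of the comparison.

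The comparison asks which genes differed between tumour Treg cells with high and with low FOXP3. FOXP3-high libraries held more transcripts of melanoma and melanocyte genes, and of T cell, resting T cell and Treg genes. The summed melanoma and melanocyte genes stood at 2036 ± 475 CPM in FOXP3-low and 4197 ± 657 CPM in FOXP3-high. The median of the Treg list fell below 0 under the T cell scaling given below. Fewer transcripts in FOXP3-high came from cell cycle genes and from macrophage, neutrophil, dendritic cell and MHC class II genes. Of 15838 genes tested, 7357 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, with 3459 higher and 3898 lower in FOXP3-high. Which direction held more genes depended on the normalization, with 3898 higher and 3591 lower under upper quartile factors. The lower genes moved further. Among the called genes, 1601 had a log2 fold change below -1 and 708 one above 1. In 8029 genes, called or not, every library of one group lay above every library of the other, where chance gives 5.71% of genes. When the null hypothesis was an absolute log2 fold change of up to 1 (glmTreat), 137 genes were higher and 981 lower. When the libraries were instead scaled to 17 T cell identity genes, an alternative chosen after the data were seen, the median of all genes moved by -0.47 and the split became 797 higher against 7922 lower.

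**Figure D1:**
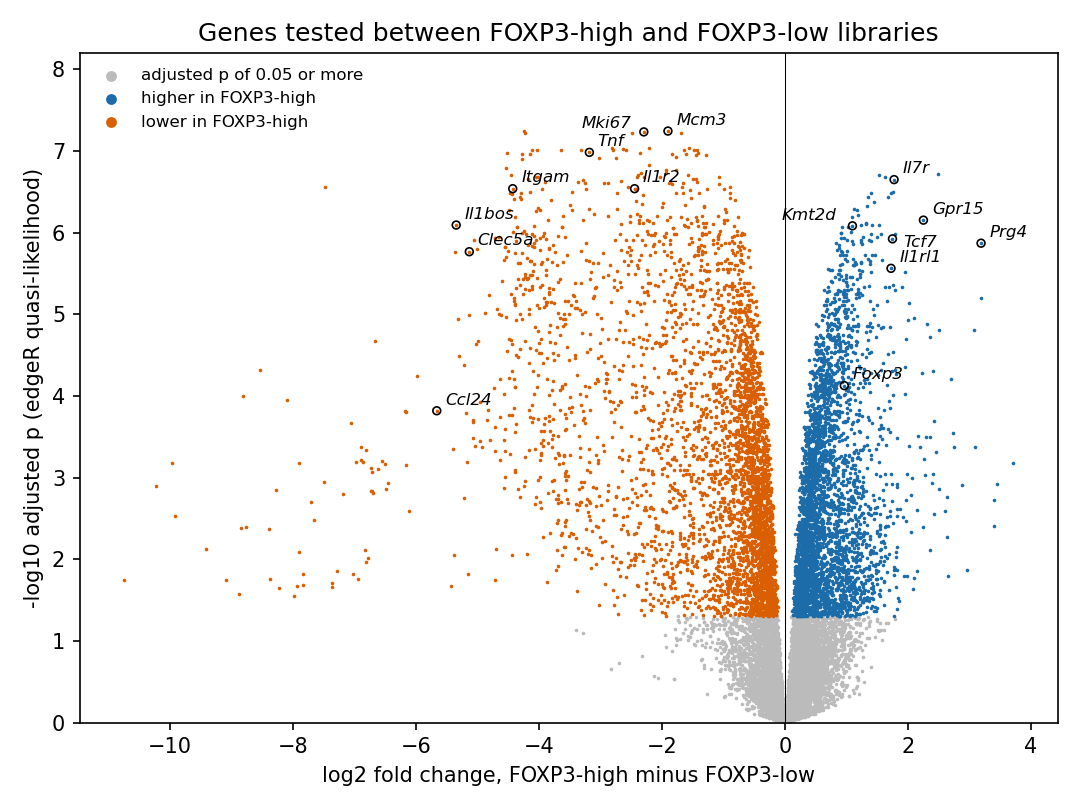
Log2 fold change (FOXP3-high minus FOXP3-low, x axis) against -log10 adjusted p of edgeR's quasi-likelihood test (y axis) for the 15838 genes tested, with blue for the 3459 genes higher and orange for the 3898 genes lower in FOXP3-high. Named genes are circled, and the lower genes reach further from 0 than the higher genes.

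The largest increases in FOXP3-high, among genes with a mean of at least 5 CPM and no overlap between the groups, came from genes of several kinds. Prg4, which encodes the lubricating glycoprotein lubricin, rose from 6.45 ± 1.43 to 59.2 ± 13.3 CPM (log2 fold change 3.19 ± 0.19, edgeR adjusted p = 1.35e-06). Gpr15, a homing receptor that guides T cells to the colon, rose 4.76-fold to 28.1 ± 2.25 CPM (edgeR adjusted p = 7.03e-07). S1pr1, the sphingosine 1-phosphate receptor used to leave tissue, rose 3.92-fold to 92.5 ± 4.75 CPM. Ccr3, a chemokine receptor, rose 5.31-fold to a low level of 11.1 ± 1.35 CPM. Other genes of this set were Prss12, St8sia6, F2rl1, Pde2a and Cd55, with increases between 4.07-fold and 5.13-fold and edgeR adjusted p-values of at most 5.16e-05. Pde2a overlaps the gene model Gm45837 on the same strand, which stood at 19.4 and 78 CPM against 18 and 77.9 CPM of Pde2a itself, and Prg4 overlaps Tpr on the opposite strand, so the reads of each pair were not separated with certainty.

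The largest decreases in FOXP3-high, by the same rule, included several genes that macrophages express. Ccl24, an eosinophil-attracting chemokine of macrophages, was at 13.5 ± 4.53 CPM in FOXP3-low and rested on 8 counts in FOXP3-high, all in replicate 3 (log2 fold change -5.66 ± 0.71, edgeR adjusted p = 1.52e-04); without that library the fold change of Ccl24 would be only a bound. Clec5a, a myeloid lectin, fell from 47 ± 7.66 to 1.28 ± 0.821 CPM, and Fcgr1, the high-affinity IgG receptor, from 32 ± 5.36 to 0.916 ± 0.569 CPM. Mrc1, the macrophage mannose receptor, fell from 106 ± 18.3 to 3.2 ± 1.71 CPM (edgeR adjusted p = 1.59e-06). F13a1 fell from 111 ± 10.1 CPM by a log2 fold change of -4.88, and Tgfbi from 350.2 ± 68 CPM by -4.66. Il1bos, Flrt3, Septin3 and Mcemp1 completed this set, with log2 fold changes between -5.34 and -4.71. Il1bos lies antisense to Il1b and Flrt3 inside Macrod2 on the opposite strand, and the strand setting of the counting is not given in the sources used here.

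Lists of markers of other cell types, fixed before the data were examined, differed between the groups in both directions. All 21 tested macrophage and monocyte genes were lower in FOXP3-high (21 when adjusted over the list alone), with a median log2 fold change of -3.95 (camera adjusted p = 3.70e-14; adjusted p = 0.24 with an estimated correlation). Itgam, which encodes CD11b, was at 543 ± 53.3 CPM in FOXP3-low and 25.1 ± 7.71 in FOXP3-high, and Lyz2, lysozyme of phagocytes, at 553 ± 38.9 and 28 ± 9.02. Itgam overlaps Gm49368 on the same strand. Of 9 neutrophil genes 8 were lower (8 when adjusted over the list alone; median -3.93, camera adjusted p = 4.77e-06; adjusted p = 0.24 with an estimated correlation). Il1b, the inflammatory cytokine interleukin-1 beta, was at 2020 ± 204 CPM in FOXP3-low and 96.4 ± 43 in FOXP3-high. Of 11 dendritic cell genes 10 were lower, and of 9 MHC class II presentation genes 8 (10 and 8 when adjusted over the list alone), with medians of -2.77 and -3.06 (camera adjusted p = 2.68e-04 and 4.02e-05; adjusted p = 0.34 for both with an estimated correlation). H2-Ab1, an MHC class II chain, was at 1462 ± 289.5 CPM in FOXP3-low and 94.7 ± 32.3 in FOXP3-high.

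Of 7 B cell and plasma cell genes, 4 were lower in FOXP3-high (4 when adjusted over the list alone; median -1.03, camera adjusted p = 0.032; adjusted p = 0.24 with an estimated correlation). They were Jchain, which joins IgA and IgM, at 57 ± 19.1 against 3.42 ± 0.914 CPM, Igkc, the kappa light chain, at 241 ± 51 against 16.9 ± 9.36, Ighm, and Mzb1, which rested on 3 counts in FOXP3-high and overlaps Gm50318 on the same strand. The camera call of the B cell and plasma cell list was lost without FOXP3-high replicate 2 (median -0.80, adjusted p = 0.0502), without receptor and immunoglobulin segments (-0.58, adjusted p = 0.24) and with T cell identity scaling (adjusted p = 0.22). Of 5 CD8 T cell genes 4 were lower (4 when adjusted over the list alone; median -1.62, camera adjusted p = 0.032; adjusted p = 0.38 with an estimated correlation), with Cd8a at 11 ± 0.789 and 3.11 ± 0.663 CPM. The camera call of the CD8 T cell list was lost with T cell identity scaling (adjusted p = 0.20). Melanoma and melanocyte genes went the other way. Of 14 tested, 12 were higher in FOXP3-high (12 when adjusted over the list alone; median 1.07, camera adjusted p = 4.72e-05; adjusted p = 0.35 with an estimated correlation), and Dct, a pigment enzyme, was at 1476 ± 351 CPM in FOXP3-low and 3061 ± 472 CPM in FOXP3-high.

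Endothelial, fibroblast and pericyte genes varied between libraries of one group. None of 10 endothelial genes passed (0 when adjusted over the list alone; edgeR), with 0 at an unadjusted p under 0.05 and 0 at an adjusted p under 0.05 with DESeq2 or limma-voom. Pecam1, an endothelial adhesion molecule in this list, passed in 3 alternatives: without FOXP3-low replicate 3 (log2 fold change 0.84, adjusted p = 0.0099), with the replicate number as a block (0.43, adjusted p = 0.048) and without both libraries numbered 3 (0.59, adjusted p = 0.014). The summed endothelial genes stood at 434 CPM in FOXP3-low replicate 3 and 484 CPM in FOXP3-high replicate 3, against 75.5 CPM in FOXP3-high replicate 2. Of 12 fibroblast and pericyte genes 1 was lower (1 when adjusted over the list alone), Fn1 at 642 ± 137 against 142 ± 102 CPM. Leaving out both libraries numbered 3, an alternative chosen after the data were seen, gave 6502 changed genes. NK cell genes gave 0 higher and 2 lower of 6 (0 higher and 1 lower when adjusted over the list alone), erythroid and platelet genes 0 higher and 1 lower of 7 (0 higher and 1 lower when adjusted over the list alone), and keratinocyte genes 2 higher and 1 lower of 4 (2 higher and 1 lower when adjusted over the list alone). None of the 3 tested gamma-delta T cell genes passed (0 when adjusted over the list alone, and 0 at an unadjusted p under 0.05 in edgeR), with Trdc at 3.84 ± 0.971 and 2.69 ± 0.549 CPM; with T cell identity scaling Trdc passed as lower (log2 fold change -0.97, adjusted p = 0.019). Trdc overlaps Trdv5 on the opposite strand. The single tested mast cell and basophil gene, Kit, was at 14.6 ± 4.56 and 13.6 ± 1.49 CPM.

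**Figure D2:**
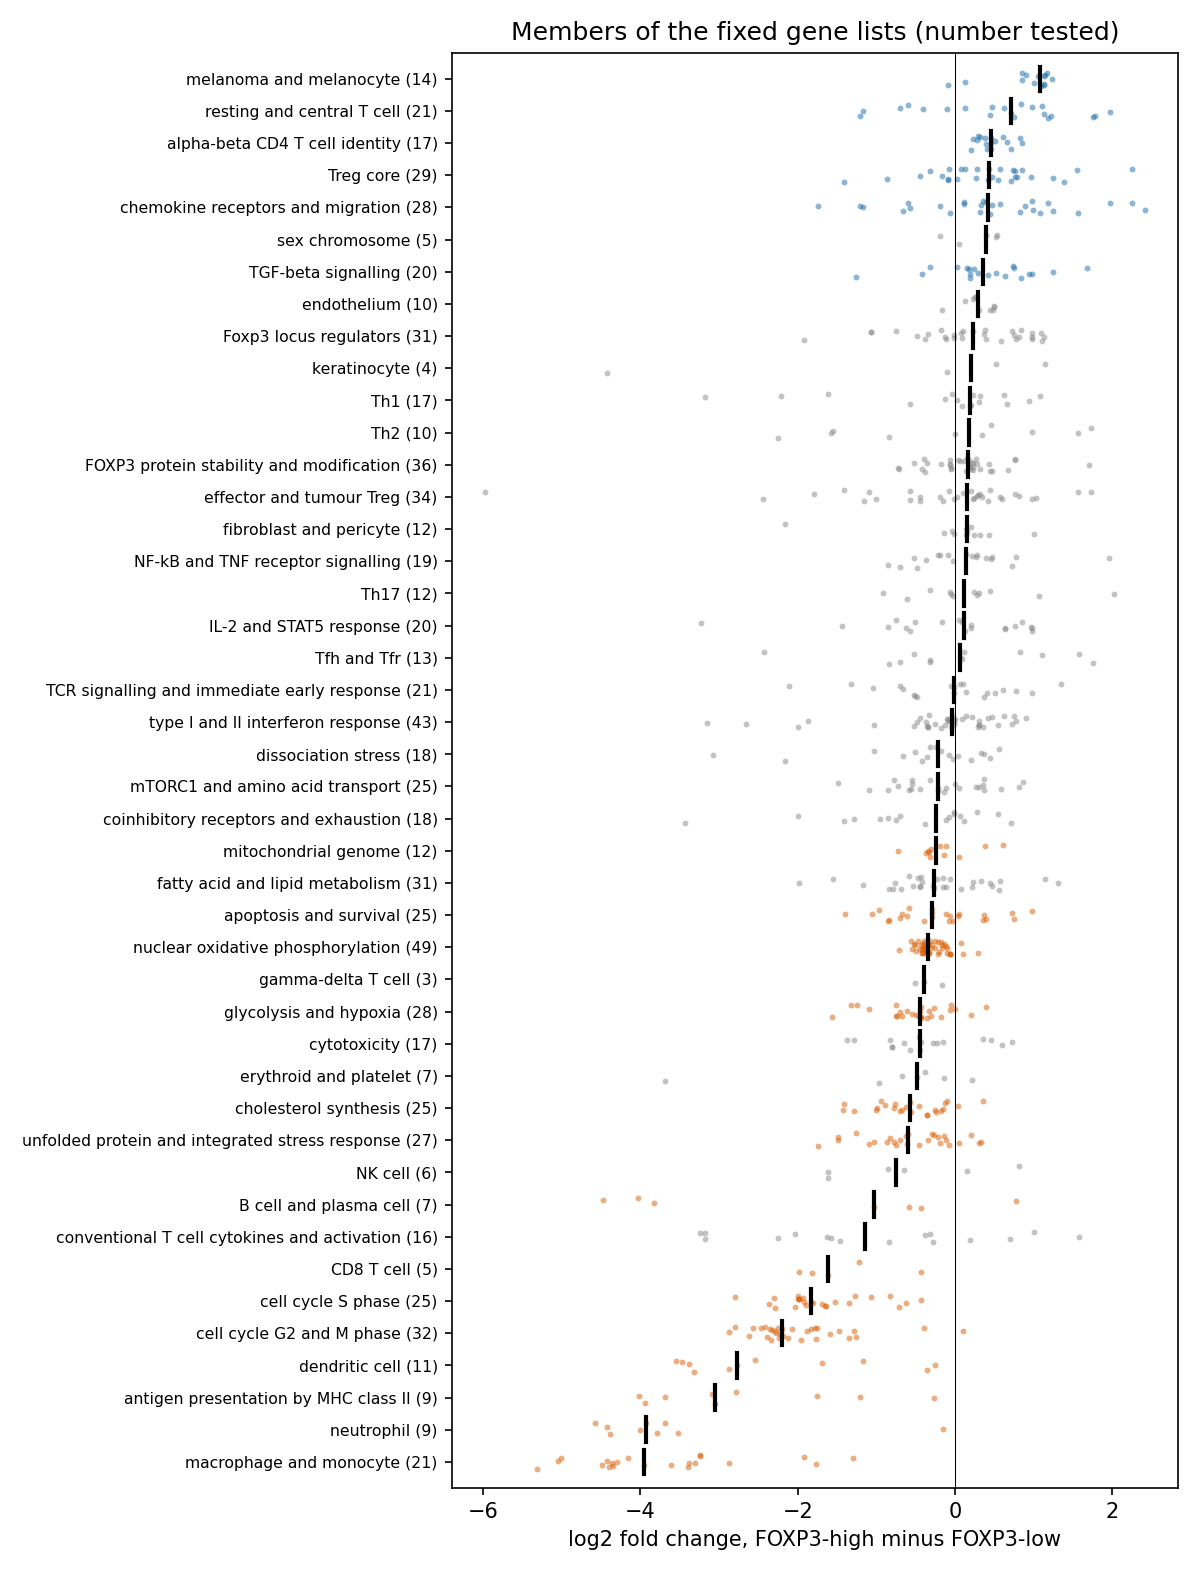
Log2 fold change (FOXP3-high minus FOXP3-low, x axis) of each tested member of 44 gene lists (points, jittered vertically; number of members in parentheses) with the list median as a black bar. Blue and orange mark lists that passed camera at an adjusted p of 0.05 with a median above and below 0, grey the others; medians run from -3.95 for macrophage and monocyte genes to 1.07 for melanoma and melanocyte genes.

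Of the 57 cell cycle genes tested, 55 were lower in FOXP3-high. All 25 S phase genes fell (25 when adjusted over the list alone), with a median log2 fold change of -1.83 (camera adjusted p = 5.97e-18; adjusted p = 0.075 with an estimated correlation). Of 32 G2 and M phase genes 30 fell (30 when adjusted over the list alone), with a median of -2.19 (camera adjusted p = 8.07e-20; adjusted p = 0.24 with an estimated correlation). Mki67, the proliferation marker, was at 2880 ± 120.1 CPM in FOXP3-low and 588 ± 39.4 CPM in FOXP3-high, 4.9-fold lower (log2 fold change -2.29 ± 0.0588, edgeR adjusted p = 5.84e-08). Top2a, which untangles replicated DNA, was 4.62-fold lower and Kif11, a spindle motor, 6.17-fold lower. Mcm3, part of the replicative helicase, fell from 326 ± 4.88 to 87.4 ± 3.11 CPM, and Clspn, a replication checkpoint adaptor, from 272 ± 6.71 to 38.9 ± 5.11 CPM. The cell cycle genes moved in the same direction as the macrophage genes given above.

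Lists of glycolysis, oxidative phosphorylation, cholesterol synthesis and unfolded protein genes also had more members lower than higher in FOXP3-high. Of 28 glycolysis and hypoxia genes 21 were lower and 1 higher (22 lower and 2 higher when adjusted over the list alone; median -0.45, camera adjusted p = 1.92e-06; adjusted p = 0.24 with an estimated correlation). Ldha, lactate dehydrogenase, fell from 567 ± 7.64 to 350.2 ± 19.2 CPM, and Slc16a3, a lactate exporter, from 89.2 ± 5.2 to 35.6 ± 0.951 CPM (Slc16a3 overlaps Csnk1d on the opposite strand). Of 49 nuclear genes of oxidative phosphorylation 33 were lower (33 when adjusted over the list alone; median -0.35, camera adjusted p = 3.91e-06; adjusted p = 0.24 with an estimated correlation), among them the ATP synthase gene Atp5f1a with a log2 fold change of -0.50 ± 0.0499. Of 25 cholesterol synthesis genes 16 were lower (17 when adjusted over the list alone; median -0.57, camera adjusted p = 8.06e-06; adjusted p = 0.075 with an estimated correlation), and Idi1, an isoprenoid enzyme, fell from 55.5 ± 1.48 to 20.6 ± 3.35 CPM. Of 27 unfolded protein and integrated stress response genes 17 were lower and 2 higher (19 and 2 when adjusted over the list alone; median -0.60, camera adjusted p = 4.77e-06; adjusted p = 0.24 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell from 954 ± 36.3 to 584 ± 18.9 CPM, and Phgdh, the first enzyme of serine synthesis, from 125 ± 2.15 to 44.6 ± 2.62 CPM. The macrophage genes given above moved in the same direction as these lists.

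Of 25 apoptosis and survival genes 12 were lower and 3 higher (12 and 3 when adjusted over the list alone; median -0.29, camera adjusted p = 0.021; adjusted p = 0.30 with an estimated correlation). The survival genes Bcl2l1 and Mcl1 were 1.81-fold and 1.8-fold lower. The apoptosis and survival list moved in the same direction as the macrophage, neutrophil and MHC class II genes given above. Of 12 genes of the mitochondrial genome 8 were lower (9 when adjusted over the list alone; median -0.25, camera adjusted p = 0.024; adjusted p = 0.24 with an estimated correlation). The camera call of the mitochondrial genome list was also lost with a correction for gene length and GC content (median -0.145, adjusted p = 0.22) and with T cell identity scaling (median -0.72, adjusted p = 0.072).

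T cell genes were higher in FOXP3-high, where the macrophage genes given above were lower and the melanoma genes higher. Of 17 genes of alpha-beta CD4 T cell identity, 16 were higher and none lower (17 higher when adjusted over the list alone; median 0.45, camera adjusted p = 4.91e-07; adjusted p = 0.35 with an estimated correlation). Cd2, a T cell adhesion receptor, rose from 688 ± 53.2 to 1090 ± 104 CPM. Resting and central T cell genes gave 12 higher and 3 lower of 21 tested (13 higher and 4 lower when adjusted over the list alone; median 0.71, camera adjusted p = 0.0018; adjusted p = 0.24 with an estimated correlation). Il7r, the interleukin-7 receptor, rose from 127 ± 8.06 to 434 ± 40.1 CPM (log2 fold change 1.77 ± 0.072, edgeR adjusted p = 2.24e-07). Tcf7, which encodes TCF1, rose from 39.9 ± 4.38 to 134 ± 14 CPM, and its relative Lef1 from 35.6 ± 1.81 to 76.6 ± 10.1 CPM. Among the members that fell, named after their values were seen, were the homing receptors Ccr7 (log2 fold change -1.18) and Ccr9 (-1.21); Ccr9 overlaps Gm17200 on the same strand and Gm10052, Lztfl1 and Gm17021 on the opposite strand. With T cell identity scaling the median of this list stayed above 0, at 0.24, with 9 members higher and 7 lower.

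Treg core genes gave 17 higher and 3 lower of 29 (18 higher and 3 lower when adjusted over the list alone), with a median log2 fold change of 0.43 that turned to -0.0415 with T cell identity scaling, where 10 were higher and 12 lower (both tests that follow are with TMM; camera adjusted p = 0.0022; adjusted p = 0.51 with an estimated correlation). Itgae, which encodes the tissue-retention integrin CD103, rose from 69.3 ± 4.22 to 164 ± 17.5 CPM. Nt5e, which encodes the adenosine-producing enzyme CD73, rose from 29.5 ± 2.58 to 77 ± 14.4 CPM, while Entpd1, which encodes CD39 upstream of it, fell from 110.5 ± 6.89 to 41.4 ± 2.67 CPM (log2 fold change -1.41 ± 0.075, edgeR adjusted p = 8.39e-07). Itgae overlaps Haspin on the opposite strand. With TMM more of the resting T cell and Treg core genes rose than fell, where the macrophage genes fell and the melanoma genes rose. The list shared 19 of its 29 members with other lists, and without Foxp3 and the shared members its camera adjusted p was 0.13. Effector and tumour Treg genes went both ways, with 13 higher and 10 lower of 34 (15 higher and 10 lower when adjusted over the list alone; median 0.15 and mean -0.19, camera adjusted p = 0.71). Under T cell identity scaling 6 of them were higher and 21 lower (median -0.32). Among the effector and tumour Treg genes Il1r2, the interleukin-1 decoy receptor, fell from 102 ± 7.46 to 18.6 ± 2.58 CPM and Penk, proenkephalin, from 1020 ± 69.1 to 479 ± 39.5 CPM, while Ccr4, a chemokine receptor, rose from 16.2 ± 1.01 to 47.8 ± 4.06 CPM. Entpd1, Il1r2 and Penk moved in the same direction as the macrophage genes given above, and bulk counts do not show which cells held their transcripts.

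**Figure D3:**
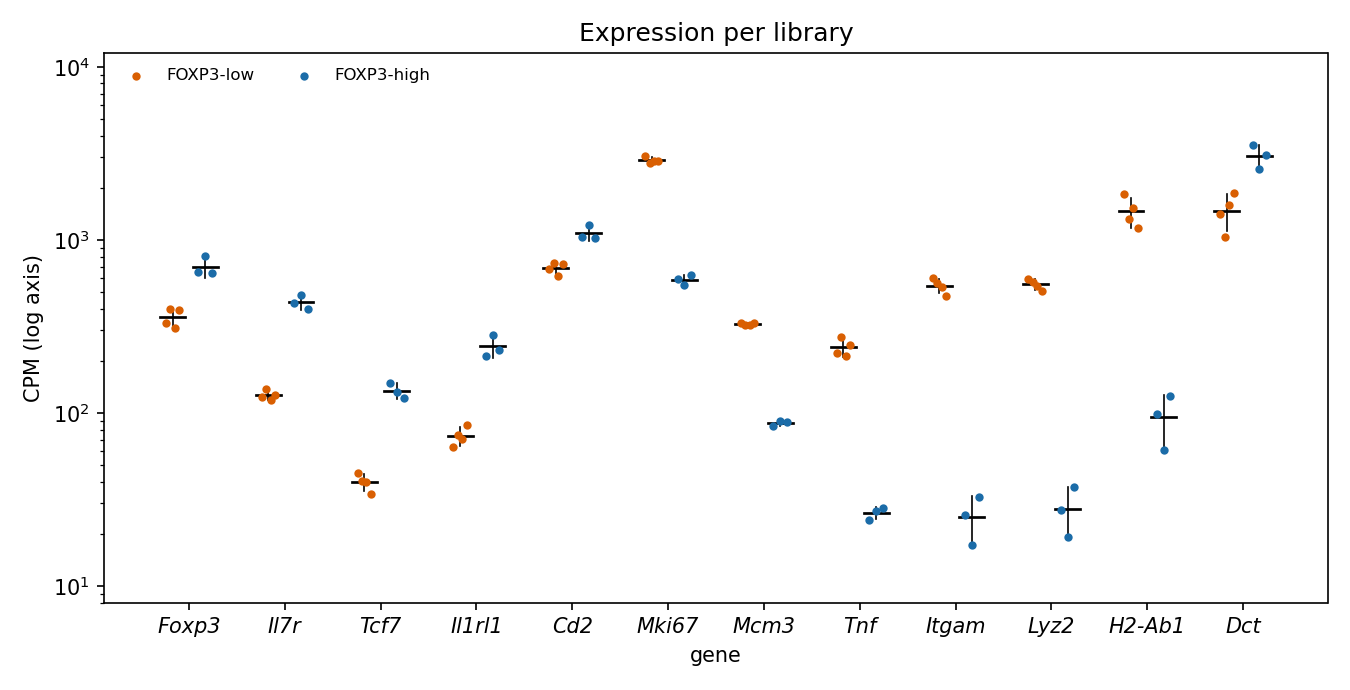
CPM on a log axis for 12 genes, with one point per library (4 FOXP3-low in orange, 3 FOXP3-high in blue), the group mean as a horizontal bar and 1 SD as a vertical line. Mki67 averages 2880 CPM in FOXP3-low and 588 in FOXP3-high, while Il7r averages 127 and 434.

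Chemokine receptor and migration genes gave 16 higher and 6 lower of 28 (16 higher and 6 lower when adjusted over the list alone), and their median of 0.42 turned to -0.0573 with T cell identity scaling (camera adjusted p = 0.0023; adjusted p = 0.37 with an estimated correlation). Gpr15, Ccr4 and Itgae rose, and Cd44, a hyaluronan receptor, fell from 405 ± 7.5 to 255 ± 4.05 CPM. TGF-beta signalling genes gave 12 higher and 3 lower of 20 (12 higher and 3 lower when adjusted over the list alone), with a median of 0.35 that turned to -0.12 with the same scaling (camera adjusted p = 0.0013; adjusted p = 0.32 with an estimated correlation). Ldlrad4, an inhibitor of TGF-beta signalling, rose from 24 ± 0.695 to 76.9 ± 6.95 CPM and Smad3, a transducer of it, from 31.6 ± 1.69 to 62.3 ± 3.73 CPM. Ldlrad4 overlaps Fam210a on the opposite strand.

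Lists of helper T cell programmes did not pass camera, although single members differed. The Th2 list gave 4 higher and 2 lower of 10 (4 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.26), with Il1rl1, the receptor for interleukin-33, at 73.1 ± 9.12 and 242 ± 36 CPM and Gata3 at 124 ± 16.8 and 244 ± 42.3 CPM, both higher. The Th17 list gave 3 higher and 0 lower of 12 (2 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.43), the Tfh and Tfr list 4 higher and 1 lower of 13 (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.38) and the Th1 list 6 higher and 4 lower of 17 (7 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.35). Cd40lg, the ligand that T cells use to activate B cells, rose from 21.6 ± 1.39 to 64.1 ± 8.63 CPM. Conventional T cell cytokine and activation genes gave 3 higher and 8 lower of 16 (3 higher and 9 lower when adjusted over the list alone; median -1.15, camera adjusted p = 0.07). Tnf fell from 239 ± 28.1 to 26.4 ± 2.08 CPM and the chemokine gene Ccl3 from 244 ± 32.8 to 25.7 ± 4.07 CPM, both of which macrophages also express. Ccl3 overlaps Gm53692 and Gata3 overlaps Gm13256, each on the opposite strand.

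Among signalling and effector lists, cytotoxicity genes gave 3 higher and 7 lower of 17 (3 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.15), with Gzmb at 227 ± 9.83 and 344 ± 58.5 CPM and Prf1 at 22.8 ± 2.93 and 9.34 ± 1.65 CPM. Coinhibitory receptor and exhaustion genes gave 3 higher and 9 lower of 18 (3 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.061, with a median of -0.25). The coinhibitory receptors and exhaustion list passed without the members it shares with other lists (median -0.85, adjusted p = 0.0026) and in 4 other camera alternatives, and Havcr2, which encodes TIM-3, fell from 175 ± 11.4 to 71.6 ± 3.7 CPM. Havcr2 moved in the same direction as the macrophage genes given above, and bulk counts do not show which cells held its transcripts. T cell receptor signalling and immediate early genes gave 7 higher and 8 lower of 21 (7 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.87), where Cd69, an early activation and retention marker, was 2.54-fold higher and Egr2 was 4.33-fold lower. NF-kB and TNF receptor genes gave 8 higher and 6 lower of 19 (8 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.64), with Tnfrsf25 3.89-fold higher. Interleukin-2 and STAT5 genes gave 8 higher and 7 lower of 20 (8 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.74), with Stat5b at 140.1 ± 5.59 and 276 ± 36 CPM. Type I and II interferon genes gave 14 higher and 13 lower of 43 (14 higher and 14 lower when adjusted over the list alone; camera adjusted p = 0.98), with Oasl1 and Rsad2 6.33-fold and 3.65-fold lower and Gbp6, which overlaps Gm43302 on the same strand, 1.86-fold higher. Under T cell identity scaling 5 of the interferon genes were higher and 31 lower (median -0.51).

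Genes that act on Foxp3 or its protein also split. Regulators of the Foxp3 locus gave 16 higher and 8 lower of 31 (16 higher and 8 lower when adjusted over the list alone; camera adjusted p = 0.061). Under T cell identity scaling this balance turned, to 10 higher and 16 lower (median -0.24). The DNA methylation maintenance genes Dnmt1 and Uhrf1 fell from 707 ± 24.3 to 336 ± 1.88 CPM and from 148 ± 7.33 to 39.1 ± 5.66 CPM, as did Ezh2, a histone methyltransferase, from 275 ± 4.39 to 130.5 ± 4.56 CPM. Uhrf1 is also a member of the S phase list, and Dnmt1 and Ezh2 moved in the same direction as the cell cycle genes given above. Kmt2d, a methyltransferase of enhancers, rose from 327 ± 8.74 to 700.3 ± 60.1 CPM. Genes of FOXP3 protein stability and modification gave 14 higher and 7 lower of 36 (15 higher and 7 lower when adjusted over the list alone; camera adjusted p = 0.16), with the acetyltransferase gene Crebbp 1.6-fold higher and Dtx1, an E3 ligase of Notch signalling, at 5.25 ± 0.771 and 17.1 ± 1.44 CPM. Under T cell identity scaling this protein stability list gave 2 higher and 23 lower (median -0.31). Fatty acid and lipid genes gave 5 higher and 14 lower of 31 (5 higher and 16 lower when adjusted over the list alone; camera adjusted p = 0.061), with the lipid droplet gene Plin2 3.95-fold lower. The mTORC1 and amino acid transport list gave 7 higher and 12 lower of 25 (7 higher and 13 lower when adjusted over the list alone; camera adjusted p = 0.15), and the list of genes that respond to tissue dissociation 4 higher and 9 lower of 18 (4 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.061).

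Of the 44 lists tested, 20 passed camera with the preset correlation, and none of the 20 passed with a correlation estimated from these libraries (fry, which tests a list's own members, called the direction of all 20). The endothelial, keratinocyte, effector Treg, Th1, Th2 and interleukin-2 lists, none of which passed, had a median of another sign than their mean or than the direction camera gave. With T cell identity scaling the medians of the cell cycle lists were -2.29 for S phase and -2.66 for G2 and M phase, and those of the resting and melanoma lists stayed above 0, while the Treg core, chemokine receptor and TGF-beta medians fell just below 0.

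**Figure D4:**
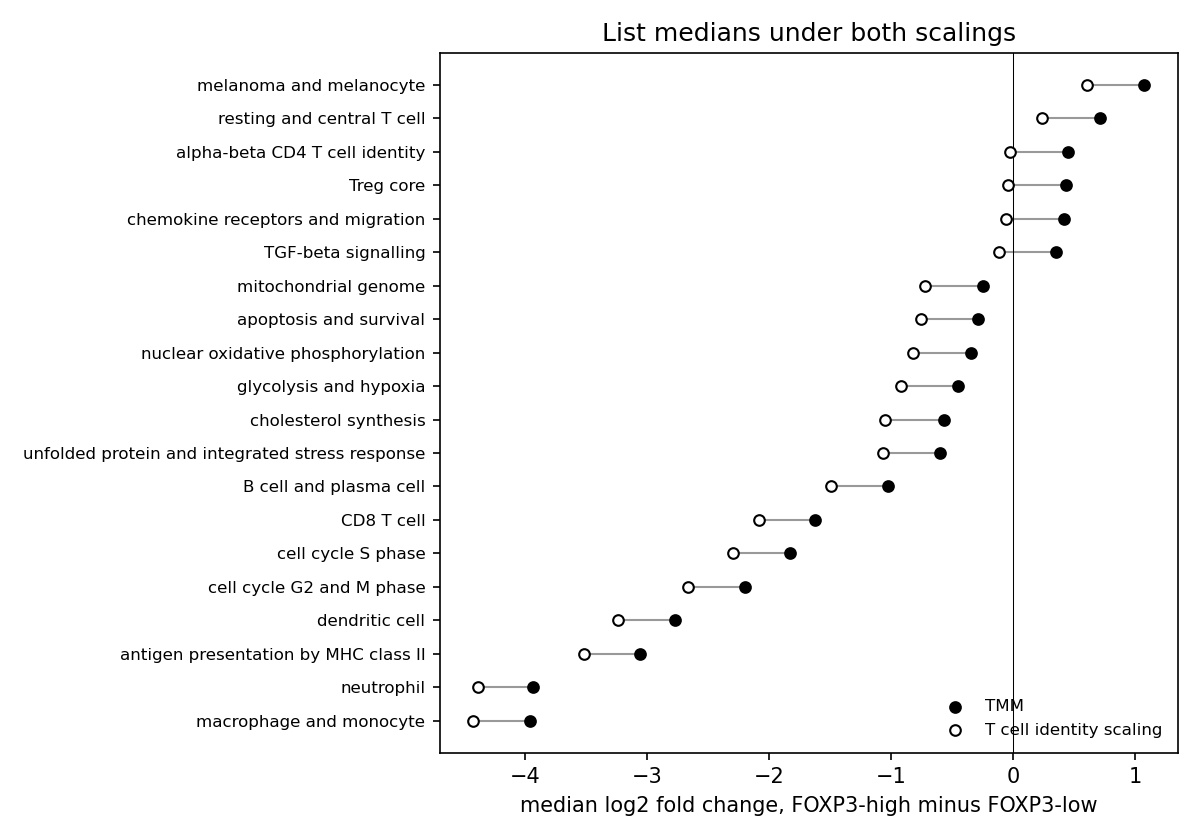
Median log2 fold change (FOXP3-high minus FOXP3-low, x axis) of the 20 lists that passed camera, with TMM normalization (filled) and with libraries scaled to 17 T cell identity genes (open). The open points lie lower by about the shift of the median of all genes, -0.47, and those of the T cell identity, Treg core, chemokine receptor and TGF-beta lists fall below 0.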

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

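The tests of other cells as a source of RNA, of T cell identity scaling and of gene length and GC content were chosen after the results were seen; those of chance and of library totals were written down before they were run. Real groups called 7357 genes, and of the 35 splits of the 7 libraries into 4 and 3 only the real one called as many. The highest of the other splits called 0 genes. The share of 1 of 35 is the smallest that these splits can give, so it argues against chance without excluding it. Every other split puts libraries of both groups together, which widens the spread within its groups and lowers its calls.

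Markers of macrophages, neutrophils, dendritic cells and MHC class II were higher in FOXP3-low. The median log2 fold change over the 4 lists was -3.43 before all libraries were thinned to 9048771 counts. After thinning it was -3.44 (quartiles -4.07 and -2.80). TMM library sizes already scale the totals, so thinning could show little beyond an effect of unequal totals on low counts. No such effect was seen in the median of these cell markers. RNA of such cells in the FOXP3-low libraries is a candidate explanation, since 47 of 50 tested members were lower in FOXP3-high, led by Il1b at 2020 CPM and H2-Ab1 at 1462 CPM in FOXP3-low, and 14 were at 10 CPM or more in FOXP3-high; no other list holds these members, and the gates of the sort are not given in the sources used here. Expression of these genes by the FOXP3-low Treg cells themselves stays open, because bulk counts hold no single cells; that 4 of 7 members of the B cell and plasma cell list were lower in FOXP3-high too does not decide it. A lower share of all other cells in FOXP3-high as one block is not what the lists showed, since melanoma genes had a median of 1.07 in the opposite direction.

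Cell cycle genes were lower in FOXP3-high. Gene length and GC content bias as the whole cause is argued against, since the median of the 57 cell cycle genes was -1.96 before and -1.95 after the correction (quartiles -2.25 and -1.63), with 55 of 57 still called. Whether dividing Treg cells or other dividing cells in the FOXP3-low libraries carried these transcripts cannot be told apart, because the myeloid markers vary with the group and little within it. With T cell identity scaling the median was -2.43. More division of Treg cells with low FOXP3 remains an open biological hypothesis.

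Of 21 resting T cell genes 12 were higher and 3 lower in FOXP3-high, and of 29 Treg core genes 17 were higher and 3 lower. A lower share of T cell RNA in the FOXP3-low libraries could raise such genes. With T cell identity scaling the median of all 21 resting genes went from 0.71 to 0.24 (quartiles -0.58 and 0.64), with 9 called higher and 7 lower. That of the 28 Treg core genes without Foxp3, which names the groups, went from 0.43 to -0.0487 (quartiles -0.55 and 0.28), with 9 called higher and 12 lower. A lower T cell share and a difference in state between FOXP3-high and FOXP3-low Treg cells cannot be told apart for either list, because the members go both ways under the scaling and spread to both sides of 0.

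In the FOXP3-low group, where 4 libraries allow a test of a single far library, 11 of 212 values tested had 1 library far from the other 3, and chance flags about 5% of groups. FOXP3-low replicate 3 stood apart in the summed endothelial list at 434 CPM against 115 to 143 in the other libraries (gap 0.912), in Pecam1 at 122 CPM against 54.1 to 63.7 in the other libraries (gap 0.86), in S1pr1 at 34.1 CPM against 19.2 to 20.6 in the other libraries (gap 0.901), in Crtam at 5.61 CPM against 4.18 to 4.23 in the other libraries (gap 0.967) and in Stat5b at 132 CPM against 142 to 144 in the other libraries (gap 0.907). FOXP3-low replicate 2 stood apart in Cd55 at 12.7 CPM against 9.34 to 9.88 in the other libraries (gap 0.839), in Gzmb at 242 CPM against 221 to 224 in the other libraries (gap 0.852) and in Uty at 15 CPM against 11.2 to 11.8 in the other libraries (gap 0.845). FOXP3-low replicate 4 stood apart in Pfkfb3 at 105 CPM against 117 to 119 in the other libraries (gap 0.854), in Psat1 at 29.1 CPM against 25.4 to 25.6 in the other libraries (gap 0.939) and in St8sia6 at 4.52 CPM against 7.31 to 7.78 in the other libraries (gap 0.857).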

How the results depend on the processing

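T cell identity scaling, the length and GC correction and leaving out both libraries numbered 3 were chosen after the data were seen. The number of changed genes lay between 6392 and 6890 when each library was left out in turn (2718 to 3318 higher, 3412 to 3674 lower), and Foxp3 kept a log2 fold change of 0.87 to 1.04. With T cell identity scaling the log2 fold change of Foxp3 was 0.49, against 0.97 with TMM. Against an absolute log2 fold change of 1, by the construction of that test, 1118 genes passed (137 higher, 981 lower), and Foxp3 at 0.97 did not. T cell identity scaling moved the median of all genes by -0.47, which by its construction left 797 genes higher and 7922 lower; of the 7357 called genes 4695 were called in the same direction and 319 in the opposite one. Under it the medians of the Treg core (-0.0415), TGF-beta (-0.12) and chemokine receptor (-0.0573) lists turned, as did Il4ra (-0.0236), Rora (-0.0298), Ahr (-0.19) and Kdm5d (-0.077), none of these 4 genes past the threshold (Il4ra overlaps Gm44876 and Ahr Gm48236 on the opposite strand). The 3 lists still passed camera (adjusted p = 0.013, 0.016 and 2.41e-04), which compares a list with other genes. The mitochondrial genome (-0.72), CD8 T cell (-2.08) and B cell and plasma cell (-1.49) lists kept their sign and lost the camera call.

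The B cell and plasma cell list also lost it without receptor and immunoglobulin segments (-0.58; fewer members were tested) and without FOXP3-high replicate 2 (median -0.80; -2.41 to -0.80 over all libraries left out), and the mitochondrial genome list with the length and GC correction (-0.145). The Treg core list lost it without shared members (0.45), where fewer members were tested. With an estimated correlation none of the 20 lists passed, with the medians as they were: Treg core (0.43), resting and central T cell (0.71), TGF-beta signalling (0.35), cell cycle S phase (-1.83), cell cycle G2 and M phase (-2.19), glycolysis and hypoxia (-0.45), nuclear oxidative phosphorylation (-0.35), mitochondrial genome (-0.25), cholesterol synthesis (-0.57), unfolded protein and integrated stress response (-0.60), apoptosis and survival (-0.29), chemokine receptors and migration (0.42), antigen presentation by MHC class II (-3.06), CD8 T cell (-1.62), B cell and plasma cell (-1.03), macrophage and monocyte (-3.95), dendritic cell (-2.77), neutrophil (-3.93), melanoma and melanocyte (1.07), alpha-beta CD4 T cell identity (0.45). The cause of these lost calls was not tested.

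Correlations of deviations were -0.10, 0.0965 and 0.53 for same-numbered libraries 1, 2 and 3. Those numbered 3 were mutual best partners, as were FOXP3-low 1 and FOXP3-high 2 (0.34), so pairing stays open. With the replicate number as a block, 7029 genes were called (3294 higher, 3735 lower), and none of the 20 lists lost its camera call. Other normalizations, filters and tools, and leaving out both libraries numbered 3, kept the counts within 1.5 times, and kept the sign and call of Foxp3 and of the 20 lists where they were run. Among the other named genes, 77 lost their call against an absolute log2 fold change of 1, and calls were lost 39 times under all other alternatives, 15 of them in Klre1 (adjusted p = 0.041 with TMM) and 14 in Ahr (adjusted p = 0.046). Besides Il4ra, Rora and Kdm5d, the genes Ski, Sfn, Ddx3y, Gzmb and Uty lost theirs with T cell identity scaling, Uty also without FOXP3-high replicate 1, and Kdm5d also with the length and GC correction. Calls were gained by Pecam1 (higher) in 3 alternatives and by Trdc (lower) with T cell identity scaling.

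Lists that did not pass camera gained calls under alternatives. Of these 24 lists, 11 passed fry and 9 fry with the replicate block, which test the members alone. Under the other alternatives 9 lists gained 28 calls in the direction they had with TMM, 23 with a median below 0 and 5 above, and 8 of them came with no filter. The 9 lists, with the calls gained, were Foxp3 locus regulators (4), Th2 (1), coinhibitory receptors and exhaustion (5), conventional T cell cytokines and activation (5), cytotoxicity (2), dissociation stress (5), erythroid and platelet (1), fatty acid and lipid metabolism (3), mTORC1 and amino acid transport (2). The coinhibitory receptor list moved furthest, from a median of -0.25 to -0.85 without shared members. Not counted here, the Th2 list also passed with T cell identity scaling at a median of the other sign (-0.30). The sign of a median or gene turned without a call on either side 51 times among these lists and 5 times among the named genes. In the simulation 17.4% of genes changed by a log2 fold change of 0.5 were recovered. It changed 200 genes per run where the data called 7357, so this recovery does not measure the sensitivity of the real test.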

Other observations

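Some gene families outside the lists, looked at after the values were seen, differed between the groups. All 8 tested Gimap genes, GTPases of lymphocyte survival clustered on chromosome 6, were higher in FOXP3-high (edgeR), with a median log2 fold change of 1.06 that stayed at 0.59 with T cell identity scaling, where 8 were still called higher. Gimap4 rose from 1976 ± 94.4 to 3658 ± 354 CPM and Gimap3 from 322 ± 21.7 to 881 ± 68.2 CPM. Proteasome subunit genes were lower in FOXP3-high in 32 of 37 cases and higher in none, with a median of -0.50 (-0.97 with T cell identity scaling). Ribosomal protein genes gave 46 lower and 2 higher of 81, with a median of -0.26 (-0.73 with that scaling). These families were not tested for enrichment.

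T cell receptor beta chain V genes were counted in all libraries, with 1236 to 1566 counts each over 26 Trbv genes. The effective number of Trbv genes (inverse Simpson) was 10.8 ± 0.287 (SD, n = 4) in FOXP3-low and 11.8 ± 0.692 (SD, n = 3) in FOXP3-high, higher in every FOXP3-high library. A two-sided exact permutation test gave p = 0.0286, the smallest that 35 splits can give. Trbv13-2 took 16.5% ± 0.538 of Trbv counts in FOXP3-low and 12.4% ± 1.06 in FOXP3-high, and Trbv16 took 14.2% ± 1.17 and 15% ± 0.994. Near-identical V genes can share reads, and no single V gene was tested.

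Every library held both Xist and Y-linked transcripts. Xist, expressed from the inactive X of females, was at 174 to 212 CPM over the 7 libraries, Ddx3y at 87.4 to 141, Kdm5d at 31.5 to 46, Eif2s3y at 34.7 to 40.3 and Uty at 11.2 to 19.6. Xist overlaps Tsix and Gm26992 on the opposite strand. The labels do not give the sex of the mice or say whether mice were pooled. Every library also held melanoma transcripts, with Dct at 1034 to 3512 CPM. Bulk counts do not show whether host or tumour cells held the Xist and Y-linked transcripts. Of the list of 5 sex chromosome genes 3 were higher and 1 lower in FOXP3-high (3 and 1 when adjusted over the list alone; camera adjusted p = 0.22). With T cell identity scaling 0 were higher and 2 lower, and the sign of Kdm5d turned.

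Stromal genes, chosen after their values were seen, varied between libraries of one group. Col4a1, a basement membrane collagen, was at 1329 and 1375 CPM in FOXP3-low and FOXP3-high replicate 3 and at 29.8 CPM in FOXP3-high replicate 2. It overlaps Col4a2 on the opposite strand.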
